A study of Homo sapiens with 4 samples.

How the data were processed

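Gene expression was measured with Illumina bead arrays in neutrophils and monocytes isolated from the blood of healthy donors, per the labels' protocols. Neutrophils were isolated with dextran, and monocytes were enriched from mononuclear cells by magnetic negative selection. Each cell type was cultured for 60 minutes in medium with 2% serum, either alone or with 25 µM CCCP (carbonyl cyanide m-chlorophenylhydrazone, a protonophore that dissipates the mitochondrial membrane potential and uncouples respiration from ATP synthesis). RNA was extracted with a column kit, and biotinylated cRNA was hybridised. The design has 4 arrays, 1 per group. Whether the neutrophils and the monocytes came from the same donors is not given in the sources used here, and cell type, isolation method and possibly donor vary together.

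The deposited table gives an intensity and a detection p-value for each of 47320 probes on each array. The deposited intensities are background-subtracted and not scaled between arrays, as the values show: 32.3% to 38.8% of them lie below 0 and the array means differ. The deposited detection p-value falls in steps that correspond to 770 negative-control probes. The submitters' processing notes name BeadStudio; its version and settings are not given in the sources used here. The authors' series matrix holds the same intensity multiplied by 1 constant factor per array (1.15 and 1.21 for neutrophils in medium and with CCCP, 0.858 and 0.877 for monocytes), which gives all 4 arrays a mean of 92.09. Its median intensities are 2.56, 2.93, 3.54 and 3.54 in the same order. It holds 4 probes fewer, and was used as an alternative source.

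Signals were normalized with the neqc function of limma 3.58.1 in R 4.3.3. This applies a normexp background correction with control moments inferred from the detection p-values, adds an offset of 16, applies quantile normalization over the 4 arrays and takes log2. Of the 47320 probes, 30111 have 1 gene symbol in the platform annotation, 8 have several and 17201 have none here; the latter were not named. The named probes cover 20044 genes, and 142 genes that can describe a donor were left out of all results for genes and lists. The normalization, the counts of detected probes and the correlations between arrays used probes without this exclusion. Each gene is represented by its brightest probe. A comparison used genes with a detection p-value under 0.01 on every array compared. With 1 array per group no test was run: genes are described by a size rule, a difference of 1 or more on the log2 scale (2-fold). For a gene detected on only 1 of the arrays compared, the fold is a bound, the bright array against the higher of the dim probe's own value and the lowest signal of a detected probe on the dim array. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

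Before the data were examined, 40 gene lists were fixed, covering stress responses, mitochondrial and lysosomal genes, interferon and inflammatory genes, and markers of cell types that the samples could hold. Of 1033 list entries, 7 matched no current symbol and 73 have no named probe; the matching of some older symbols was completed after the data were seen. For lists with 5 or more detected members, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A list is said to stand apart when its percentile lies below 2.5 or above 97.5; this describes these libraries and is not a test. Random choice alone would put about 0.725 of 29 lists, or 0.8 of 32 in monocytes with CCCP, on each side. Named genes follow a rule also fixed beforehand. It takes the 12 highest and 12 lowest genes of each CCCP comparison, the 10 highest and 10 lowest between cell types, and the 8 highest and 8 lowest in the difference between responses. It adds the 3 largest bounds in each direction, genes with opposite responses, and any list member; uncharacterised loci and pseudogenes were passed over.

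The only repeated measure within these arrays is a pair of probes of 1 gene. The spread between such probes covers probe error and isoform differences, not the spread between cultures or donors. The number of arrays limits the precision of every value.

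The processing was tested on simulated arrays built from the medium arrays, with 200 genes changed 2-, 3- or 4-fold and a noise of 0.23 (log2 SD) per array. For the neutrophil comparison (5474 genes compared in the simulation), 30.0% of the 2-fold, 67.7% of the 3-fold and 95.8% of the 4-fold genes passed the size rule, with 0.132% of unchanged genes. For the monocyte comparison (7138 genes), the shares were 35.4%, 78.7%, 92.7% and 0.0144%. The 2-, 3- and 4-fold changes (log2 1, 1.585 and 2) were recovered at medians of 0.78, 1.18 and 1.67 in neutrophils. In monocytes the recovered medians were 0.83, 1.45 and 1.73. Simulated changes thus came out smaller than they were set. The simulated noise holds no spread between cultures or donors, so the shares of unchanged genes are not error rates for the real arrays. Of 100 random lists of 25 unchanged genes in the monocyte simulation, each placed among 1000 random lists, 6% stood apart. After 0.30 was added to the finished log2 differences of their members, 96% stood apart on the higher side. This shift bypassed the normalization, and the simulated noise was independent between genes. The 2 shares therefore describe the placing of lists and are not error rates for lists of genes that vary together.

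Alternatives fixed beforehand were no background correction, an offset of 50, median centring, quantile normalization within each cell type, a detection limit of 0.05, detection on at least 1 array, no detection filter, the mean of detected probes, and the series matrix values with a floor of 10, centred on each array's median over detected probes. A further alternative, genes with a mean log2 of 7 or more, was chosen after seeing the data.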

Results

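The series measured gene expression in human neutrophils and monocytes cultured for 60 minutes in medium or with 25 µM CCCP, with 1 array for each of the 4 groups. Its title concerns mitochondrial nucleoids released by neutrophils and type I interferon in lupus; CCCP removes the mitochondrial membrane potential. There are no replicates, so the values below describe 4 arrays. Of 47320 probes, 9009 (19.0%) were detected in neutrophils in medium and 9459 (19.99%) in neutrophils with CCCP. In monocytes the numbers were 11525 (24.4%) and 12252 (25.9%). Over the 6719 probes detected on all 4 arrays, log2 values correlated at 0.978 between the neutrophil arrays and 0.977 between the monocyte arrays, and at 0.718 to 0.732 across cell types.

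The first comparison asks which transcripts differ in neutrophils after 60 minutes of CCCP. OSM, which encodes the cytokine oncostatin M, was 5.91-fold higher with CCCP (log2 difference 2.56), and JUN (1.35), an AP-1 subunit, SOCS3 (1.34), an inhibitor of cytokine signalling, and PPP1R15A (1.17), a phosphatase subunit of the integrated stress response, were also higher. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, was 4.41-fold lower (-2.14). IER3 (-2.27), DUSP6 (-2.04), an ERK phosphatase, and TNFAIP3 (-1.81), an inhibitor of NF-kappaB signalling, were lower as well. TNF was detected in medium only and was at least 4.59-fold lower with CCCP. NR4A3, an immediate early nuclear receptor, and HBEGF, a growth factor, were detected only with CCCP, at least 3.84-fold and 2.76-fold higher.

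Of 5103 genes compared in neutrophils, 26 were at least 2-fold higher and 39 at least 2-fold lower (1.27%). The other genes with the largest positive differences were SCARNA9 (1.35), ANKRD40 (1.26), ZNF222 (1.21), DHX8 (1.20), JOSD1 (1.19), TSR1 (1.18), CBX1 (1.16) and a probe annotated to the microRNA gene MIR21 (1.72), which does not say which transcript is read. On the lower side followed SLC25A24, a mitochondrial carrier (-1.83), PELO (-1.76), DKC1 (-1.72), CYP4B1 (-1.72), EXOSC4 (-1.68), a probe annotated to MIR302C (-1.53), ZNF250 (-1.49) and CDK5R1 (-1.47). PELO lies within the gene ITGA1, so its source is uncertain. The other bounds were STXBP6 (at least 3.48-fold higher), C3AR1 (at least 3.22-fold lower) and RAP1A (at least 2.78-fold lower). Between probes of 1 gene the log2 difference had an SD of 0.33 per probe (923 genes), and only 55.9% of probe pairs had the same sign. Of 6 genes that were 2-fold by the brighter probe, 5 had the same sign and 1 was 2-fold by another probe. Another probe of SOCS3 gave 0.79, and the mean of detected probes gave -0.84 for SLC25A24. With an offset of 50, ANKRD40, ZNF222, DHX8, TSR1, CBX1, ZNF250 and CDK5R1 were under 2-fold and the counts were 8 and 15; with detection on at least 1 array they were 185 and 195.

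Among the fixed lists, the NF-kappaB inflammatory genes were lower in neutrophils with CCCP. Their median was -0.38 over 27 detected members, below all 10000 random lists and apart under 10 of 10 alternatives. Of these members 2 were 2-fold lower (IL1B and TNFAIP3) and 1 was 2-fold higher (OSM); NFKBIZ was at -0.93 and CXCL8 at -0.65. Sterol and lipid synthesis genes were lower as a list (median -0.29, percentile 0.99, 10 members, apart under 8 of 10 alternatives), with SC5D at -0.81, SREBF1 at -0.66 and none past 2-fold. Replication-dependent histones were higher as a list (0.28, percentile 98.5, 9 members, 8 of 10), with H2BC21 at 0.61 and none past 2-fold. Whether the capture of RNAs without a poly(A) tail, such as these, differed between the neutrophil arrays was not tested. Heat shock genes (0.28, percentile 98.5, 11 members) and NRF2 targets (-0.19, percentile 2.27, 16 members) stood apart under only 2 of 10 alternatives each, and hypoxia genes (0.24, percentile 97.7, 13 members) under 0 of 10. GCLM, which supplies glutathione synthesis, was the NRF2 target past 2-fold (-1.41). The medians nearest to 0 over the alternatives were -0.21 for the NF-kappaB list, 0.17 for histones, 0.11 for heat shock genes, 0.08 for hypoxia genes and -0.08 for NRF2 targets.

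The lists closest to the mitochondrial question did not stand apart in neutrophils. Mitophagy genes had a median of -0.05 over 27 members, with none past 2-fold; TBK1 was at -0.72 and RHOT1 at 0.65. The nucleoid and mtDNA maintenance list had 8 detected members and a median of 0.11, with TFAM, which packages mitochondrial DNA, at -0.44. Medians were 0.01 for mitochondrial dynamics, -0.04 for mitochondrial proteostasis, -0.01 for complex I, 0.00 for complexes II to V, 0.03 for autophagosome formation and 0.01 for lysosomal genes. Mitochondrially encoded genes have no named probe here. Interferon-stimulated genes had a median of 0.04 over 32 members, percentile 68.5, with none past 2-fold, and of the 20 type I and III interferon genes with a probe none was detected in both neutrophil arrays. The integrated stress response list had a median of 0.15 (percentile 88.5), with PPP1R15A and DDIT3 (1.04) past 2-fold and ATF4 at 0.79. The immediate early list had a median of 0.12 (percentile 91.9) with 2 members higher and 2 lower. Medians were -0.08 for the endoplasmic reticulum response, -0.02 for glycolysis, -0.11 for nucleic acid sensing, -0.06 for apoptosis regulators, 0.04 for p53 targets, -0.07 for AMPK genes, -0.06 for ribosomal proteins, -0.07 for proteasome genes, -0.12 for NADPH oxidase and -0.01 for granule proteins.

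The same question was put to monocytes, where most genes past 2-fold were lower with CCCP. IRAK2, a signalling protein of Toll-like receptor signalling, was 6.78-fold lower (-2.76), and PRDM1 (-2.68), a transcriptional repressor, TNFAIP6 (-2.65), the chemokine CCL20 (-2.33) and the chemokine receptor CCR1 (-2.30) were also lower. IL1B was at -1.65 and IL1A at -1.96. On the higher side, the growth factor HBEGF was 3.12-fold higher (1.64), as were APAF1 (1.85), the scaffold of the apoptosome, the chemokine receptor CX3CR1 (1.48) and the small RNAs SNORD13 (2.08), RNU11 (1.56) and RNU1-3 (1.52). RNU1-3 belongs to a family of near-identical copies, so its source is uncertain.

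Of 6632 genes compared in monocytes, 46 were at least 2-fold higher and 138 at least 2-fold lower (2.77%). These are more than in neutrophils among genes detected on both arrays, but detection on at least 1 array turns the order, with 380 genes past 2-fold in neutrophils and 233 in monocytes (56 higher, 177 lower). The remaining genes with the largest positive differences were PRMT5 (1.71), RNF19A (1.67), TAF12 (1.36), MITD1 (1.35), SIK1 (1.31) and TOB1 (1.30). Another probe of RNF19A gave -0.29 and another of CX3CR1 gave 0.20, whereas other probes of RNU11 and SIK1 gave 1.90 and 1.45. The mean of detected probes gave 0.63 for PRMT5, 0.69 for RNF19A, 0.84 for CX3CR1, -1.17 for PRDM1 and -1.501 for COXFA4L3. TAF12 was under 2-fold with an offset of 50. The remaining low genes were PHLDA1 (6.06-fold lower), COXFA4L3 (-2.49), EMP1 (-2.40), PELO (-2.28), TRAF3IP2 (-2.15), ZNF217 (-2.07) and RUNX1 (-2.05). Bounds were at least 4.85-fold lower for ZC3H12C, 4.02-fold for SEMA4C and 3.05-fold for FADD, and at least 2.12-fold higher for GNAT1, 1.95-fold for SNORD84 and 1.89-fold for TIGD5. The SD between probes was 0.32 (1323 genes), and 60.1% of probe pairs had the same sign. Of 31 genes 2-fold by the brighter probe, 25 had the same sign and 13 were 2-fold by another probe. With an offset of 50 the counts were 19 and 76, and from the series matrix values 123 and 248.

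The NF-kappaB inflammatory list was lower in monocytes with CCCP, with a median of -0.76 over 31 detected members, below all 10000 random lists and apart under 10 of 10 alternatives. Of its members 12 were 2-fold lower and none 2-fold higher; SOD2 was at -1.26, OSM at 0.38 and GADD45B at 0.49. Of 7 neutrophil markers detected in monocytes, 2 were also 2-fold lower, among them FFAR2 (-1.28), with PROK2 at -0.80 and MMP25 at 0.79. Autophagosome formation genes were lower as a list (median -0.22, percentile 0.61, 26 members, apart under 7 of 10 alternatives), with none past 2-fold and 10 above 0. TP53INP2 was at -0.86, ATG9A at -0.84 and WIPI1 at -0.74. Nuclear-encoded genes of complexes II to V were higher (0.18, percentile 99.2, 36 members, 9 of 10) and interferon-stimulated genes were higher (0.21, percentile 98.7, 31 members, 7 of 10), with none of either past 2-fold. TRIM22 was at 0.80 and XAF1 at 0.58, while IFIT2 was at -0.62. None of the 20 interferon genes was detected in both monocyte arrays. The medians nearest to 0 over the alternatives were -0.01 for autophagosome formation and 0.08 for interferon-stimulated genes.

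Mitophagy genes had a median of -0.02 over 26 members in monocytes (percentile 23.5), with SQSTM1 at -0.73 and none past 2-fold. The nucleoid list had a median of 0.08 over 16 members, with TFAM at -0.55 and MPV17 at 0.62. Medians were 0.06 for mitochondrial dynamics, 0.09 for mitochondrial proteostasis, 0.07 for complex I and 0.07 for lysosomal genes. Nucleic acid sensing genes had a median of 0.18 (percentile 97.1), with the inflammasome gene NLRP3 2-fold lower (-1.06). Medians were -0.09 for immediate early genes (percentile 3.62), -0.12 for the integrated stress response (6.26), -0.14 for heat shock genes (6.88), -0.17 for hypoxia genes (4.72) and -0.18 for p53 targets. HSPA1B was at -1.20 and HSPA1A at 0.48; these genes are near-identical, so the values are uncertain. Medians were -0.08 for the endoplasmic reticulum response, -0.06 for NRF2 targets, -0.08 for glycolysis, -0.07 for apoptosis regulators, -0.03 for AMPK genes, -0.14 for sterol genes, 0.00 for ribosomal proteins, -0.01 for proteasome genes, 0.08 for histones, 0.04 for NADPH oxidase and 0.12 for granule proteins. In the sterol list ABCA1 (-1.54), a cholesterol exporter, and INSIG1 (-1.22) were 2-fold lower.

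**Figure D1:**
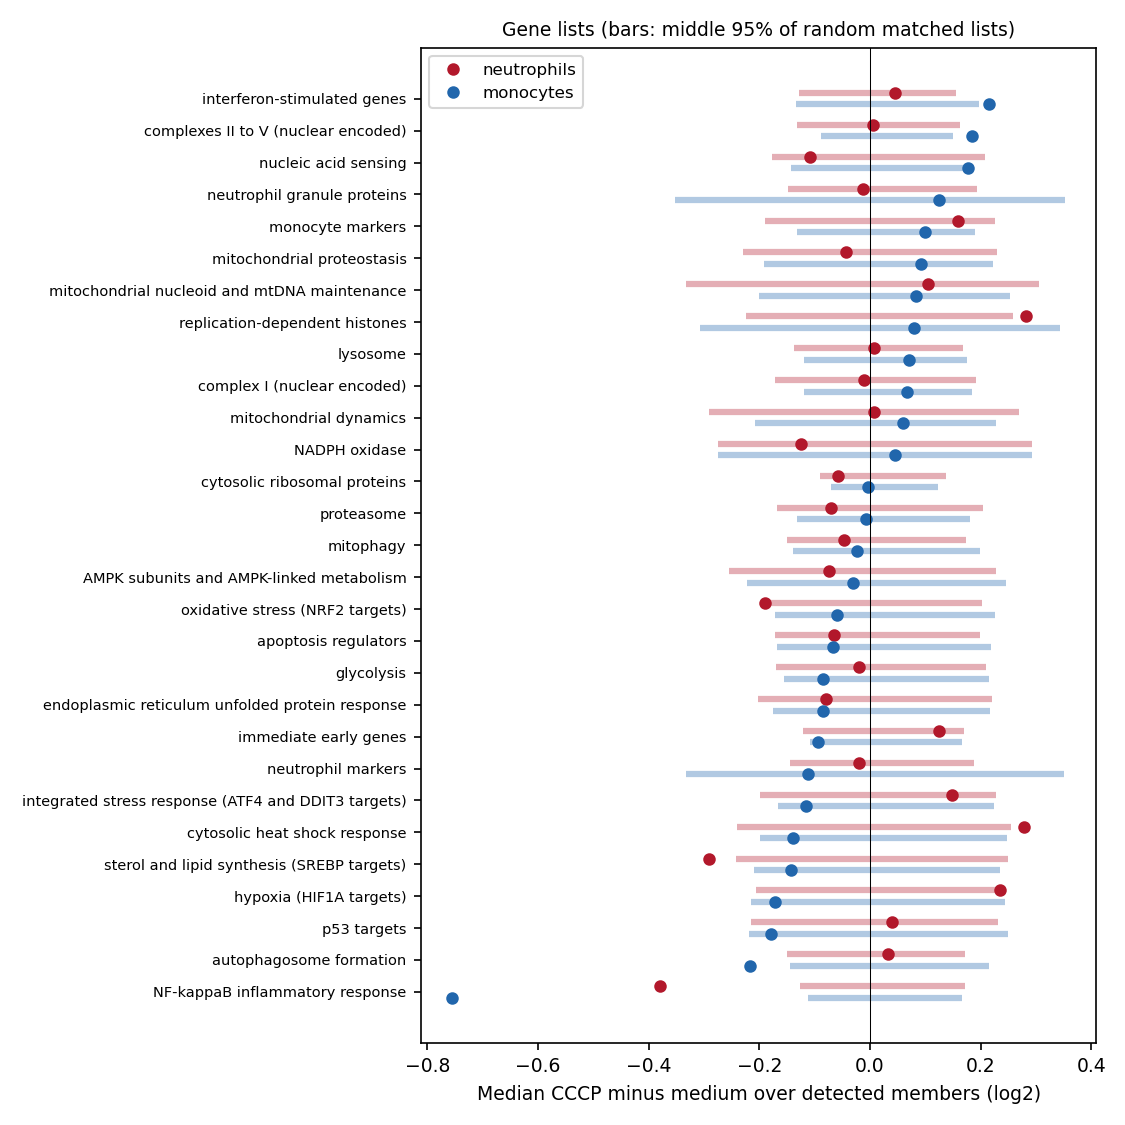
Median log2 difference (CCCP minus medium) over the detected members of each gene list in neutrophils and monocytes, 1 array per group; points are the lists' medians and bars the middle 95% of 10000 random matched lists. The NF-kappaB inflammatory list lies left of its bars in both cell types, at -0.38 and -0.76.

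The cultures could hold other cell types, whose markers were mostly detected in small numbers. HBB, an erythroid transcript, and CLC, an eosinophil transcript, were detected in both neutrophil arrays (log2 levels 9.20 and 9.10, and 9.94 and 10.23) and in neither monocyte array. Neutrophil markers had a median of -0.02 in neutrophils (21 members) and -0.11 in monocytes (7 members, lower quartile -1.04), and monocyte markers 0.16 (12 members) and 0.10 (20 members). In neutrophils the medians were -0.31 for 2 T cell markers, -0.18 for 3 NK cell markers, -0.11 for 3 platelet markers, -0.10 for 3 erythroid markers, -0.09 for 4 eosinophil markers, -0.37 for 2 basophil markers and -0.29 for 3 conventional dendritic cell markers; 1 plasmacytoid dendritic cell marker was at 0.48 and no B cell marker was detected on both arrays. In monocytes they were -0.41 for 2 B cell markers, -0.02 for 3 NK cell markers and -0.12 for 6 platelet markers. They were -0.17 for 2 eosinophil markers, -0.12 for 7 plasmacytoid and 0.32 for 5 conventional dendritic cell markers. Single erythroid and basophil markers were at -0.10 and -0.06, and no T cell marker was detected on both monocyte arrays.

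The responses of both cell types were compared over the 4501 genes detected on all 4 arrays. The genes 2-fold lower in both were IL1B, IER3, DUSP6, PELO, FBXO34 and DCUN1D3, and those 2-fold higher in both were SCARNA9 and ARHGEF40. These 6 and 2 genes compare with 0.585 and 0.135 if the calls were independent. An offset of 50 left 4 lower and 1 higher, as did a mean log2 of 7 or more. ARHGEF40 was at 1.04 in neutrophils, with a mean log2 of 5.92 in its dimmer cell type. HBEGF was outside this comparison, being undetected in neutrophils in medium. It was at least 2.76-fold higher with CCCP in neutrophils and 3.12-fold higher in monocytes. No gene was 2-fold in opposite directions, but the series matrix values gave 2 such genes and detection on at least 1 array gave 4. Across genes, which are not independent replicates, the responses correlated weakly (Pearson r 0.165, Spearman rho 0.140). Between 2 probes of 1 gene the log2 differences correlated at only 0.209 in neutrophils (923 genes) and 0.389 in monocytes (1323 genes). Probe error thus limits the correlation between cell types, and its size does not show how far the responses differ. The response was more positive in neutrophils by at least 2-fold for 147 genes and more negative for 104. With an offset of 50 the numbers were 65 and 34. Between probes of 1 gene the difference between responses had an SD of 0.45 per probe (775 genes), and 57.9% of probe pairs had the same sign. Of 37 genes 2-fold by the brighter probe, 27 had the same sign and only 7 were 2-fold by another probe.

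**Figure D2:**
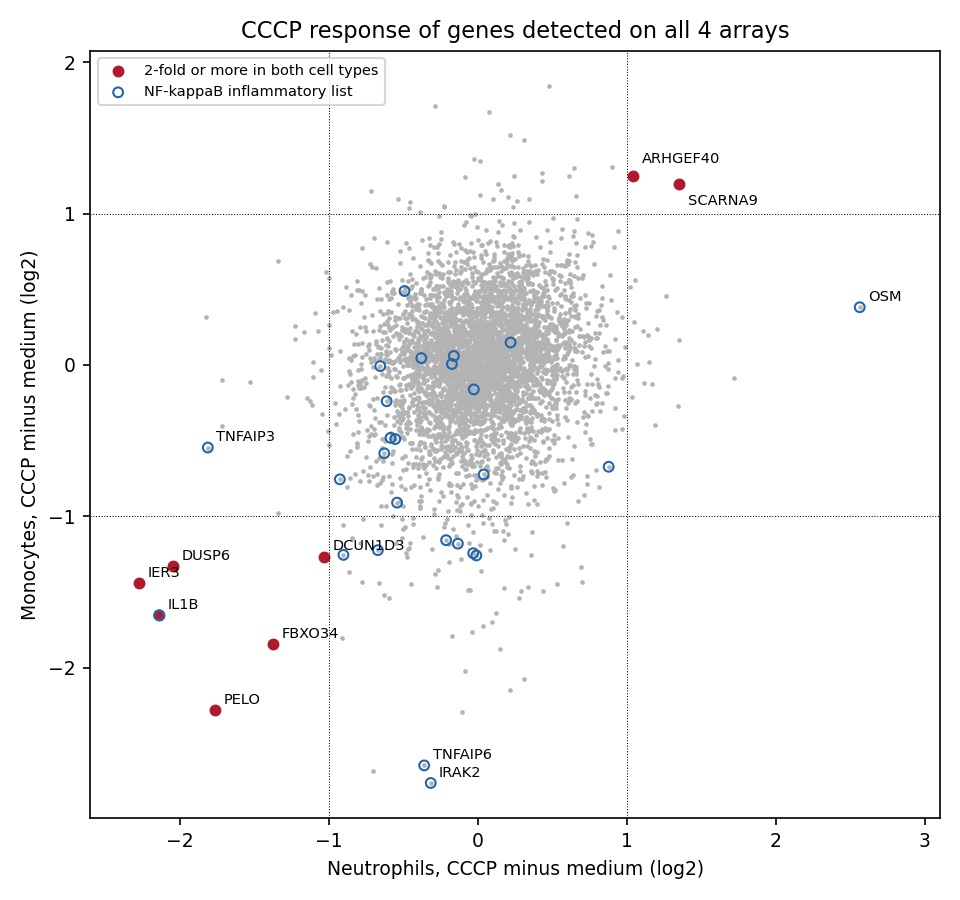
Log2 difference (CCCP minus medium) in neutrophils on the x axis and monocytes on the y axis for the 4501 genes detected on all 4 arrays, with dotted lines at 2-fold, filled points for genes past 2-fold in both and open circles for the NF-kappaB list. OSM lies at 2.56 in neutrophils and 0.38 in monocytes, and IL1B at -2.14 and -1.65.

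The genes with the most positive difference between responses were IRAK2 (2.45), ZNF217 (2.38), TRAF3IP2 (2.36), TNFAIP6 (2.29), CCR1 (2.19), OSM (2.18), CD69 (2.14) and NCK1 (2.02). The most negative were SLC25A24 (-2.14), ANKRD13D (-2.03), PRMT5 (-1.99), EMX2OS (-1.87), PRPSAP2 (-1.63), TMEM218 (-1.63), DKC1 (-1.62) and RNF19A (-1.60). For PRPSAP2 and RNF19A another probe gave -0.83 and 0.51. The mean of detected probes left NCK1 (0.73), PRMT5 (-0.88) and RNF19A (-0.54) under 2-fold and gave -1.26 for SLC25A24, and an offset of 50 gave -1.13 for EMX2OS. Of 29 lists, 7 stood apart on the positive side. Autophagosome formation (median 0.41, percentile 99.98), the integrated stress response (0.38, 99.5) and hypoxia genes (0.37, 99.3) were apart under 7, 9 and 8 of 10 alternatives, immediate early genes (0.18, 97.54) under 9, and heat shock genes (0.36, 98.5), p53 targets (0.33, 97.6) and neutrophil markers (0.51, 99.3) under 5 each. Complexes II to V stood apart on the negative side (-0.18, 1.98) under 2 of 10. Over the alternatives the smallest medians were 0.06 for autophagosome formation, 0.12 for the integrated stress response and 0.17 for hypoxia genes, each with no detection filter. They were 0.22 for heat shock genes, 0.12 for p53 targets, 0.15 for neutrophil markers and -0.09 for complexes II to V. The NF-kappaB list did not stand apart (0.10, percentile 87.4), with IRAK2, TNFAIP6 and OSM among 7 members more positive in neutrophils and TNFAIP3 (-1.27) more negative. Nor did interferon-stimulated genes (-0.01), mitophagy genes (0.03), the nucleoid list (0.05) or the endoplasmic reticulum response (0.26, percentile 96.0).

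**Figure D3:**
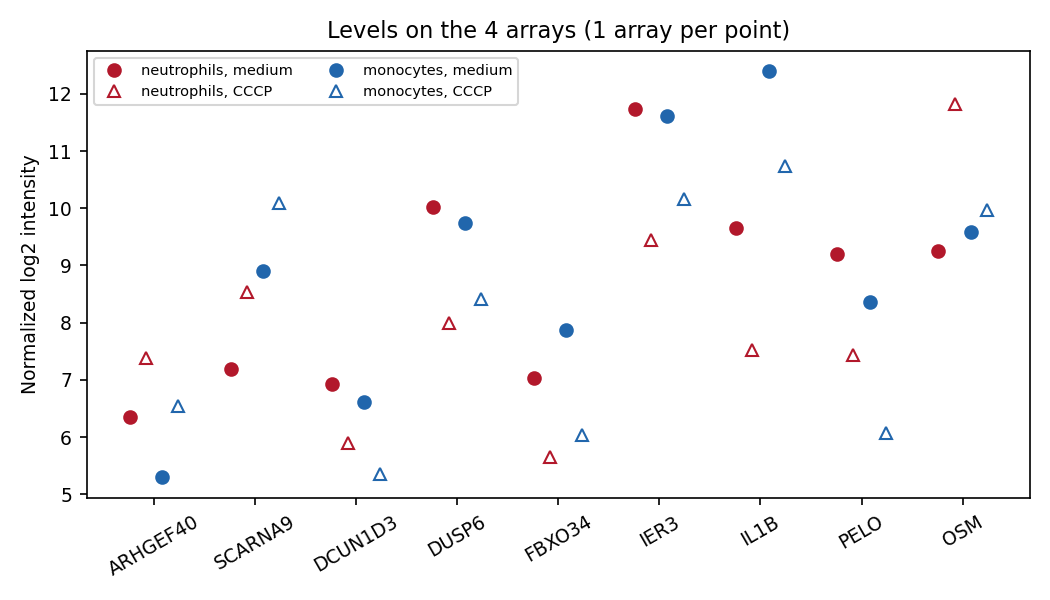
Normalized log2 intensity on each of the 4 arrays (y axis) for 8 genes and for OSM. The 8 genes were detected on all 4 arrays and past 2-fold in the same direction in both cell types. Circles are medium, triangles CCCP, and each point is 1 array. IL1B was at 9.66 and 7.52 in neutrophils and at 12.4 and 10.7 in monocytes.

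The cell types were compared in medium, where cell type, isolation and possibly donor cannot be told apart. In neutrophils MMP25 (log2 difference 6.32), the interferon-induced IFITM1 (5.74), S100P (5.33) and the chemokine-like PROK2 (5.32) were higher, followed by TGM3 (4.56), NIBAN1 (4.49), RGL4 (4.39), the formyl peptide receptor FPR2 (4.31), XPO6 (4.30) and the interferon-induced IFIT2 (4.20). In monocytes GPR183 (-5.60), the cell cycle inhibitor CDKN1A (-5.28), VCAN (-5.05), lysozyme (LYZ, -4.97), S100A10 (-4.90), LGALS1 (-4.86), HLA-DMB (-4.58), ADA2 (-4.38), TGFBI (-4.37) and TIPARP (-4.36) were higher, as the negative differences show. The defensins DEFA1 and DEFA3, near-identical copies, were at least 185-fold and 125-fold higher in neutrophils and ALPL at least 174-fold. The mean of detected probes gave -3.44 for CDKN1A. IGLL1, CYP1B1 and CPVL were at least 61.6-fold, 60.9-fold and 42.1-fold lower.

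Of 4902 genes compared, 1237 were 2-fold higher in neutrophils and 755 lower (62.1% higher), with a median over all genes of 0.31; median centring gave 0.17 and 55.7%, and detection on at least 1 array gave 49.4%. Against that shift, all 8 detected neutrophil markers were 2-fold higher (median 3.33) and monocyte markers were lower (-1.48). Ribosomal protein genes were lower in neutrophils (median -2.48, 42 of 44 members 2-fold lower), as were complex I (-1.53, 17 of 24) and complexes II to V (-1.25, 22 of 35), each below all 10000 random lists and apart under 9 of 9 alternatives. Interferon-stimulated genes were higher (1.03, percentile 99.7, 14 of 27 members 2-fold higher and none lower, 9 of 9), and so were histones (2.18, percentile 99.8, 9 of 9). For histones, different capture of RNAs without a poly(A) tail was not tested between the cell types. Granule proteins (1.73, 8 of 8), apoptosis regulators (0.87, 8 of 9), NADPH oxidase (1.502, 6 of 9) and hypoxia genes (1.25, 5 of 9) were higher, and mitochondrial proteostasis genes (-0.61, 5 of 9) lower. The granule median rests on the 5 members detected in both cell types, and detection on at least 1 array gave 3.47 over 21 members. Inflammatory NF-kappaB genes (0.04) held members on both sides, with CXCL1 at 3.99 and CCL20 at -2.87, and mitophagy genes (-0.22) did too, with MFN2 at 2.34, PINK1 at 1.44 and TOMM22 at -2.58. Medians that did not stand apart were 0.83 for AMPK genes, 0.80 for p53 targets, 0.64 for sterol genes, 0.63 for autophagosome formation, 0.54 for NRF2 targets and 0.30 for nucleic acid sensing, where NLRP3 was at -3.05, and 0.11 for mitochondrial dynamics. They were -0.44 for the endoplasmic reticulum response, -0.36 for glycolysis, -0.34 for the integrated stress response, -0.22 for proteasome, -0.12 for lysosomal genes, -0.09 for immediate early genes and -0.08 for the nucleoid list. Heat shock genes had a median of -0.72 (percentile 2.34, apart under 4 of 9), which turned to 0.31 with the mean of detected probes. The medians nearest to 0 over the alternatives were 0.38 for histones, 0.40 for hypoxia genes, 0.52 for apoptosis regulators, 0.63 for interferon-stimulated genes, 0.78 for NADPH oxidase and -0.94 for monocyte markers. The SD between probes was 0.51 (876 genes), and of 381 genes 2-fold by the brighter probe 364 had the same sign by another.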

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

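The results here were singled out because their values with CCCP had opposite signs in the neutrophil and the monocyte array pairs. This selection was set after the data were seen: a stricter one, 2-fold in opposite directions in both cell types, had found no gene with the normalization used, although the series matrix values gave 2 and detection on at least 1 array gave 4. It takes lists that stood apart in the difference between responses, and genes named for that difference whose values exceed the SD between probes in both cell types. With 1 array per group the differences were not tested, and no explanation was weighed.

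List medians (log2, CCCP minus medium) in neutrophils and monocytes were 0.12 and -0.09 for immediate early genes, 0.15 and -0.12 for the integrated stress response, and 0.28 and -0.14 for heat shock genes. They were 0.24 and -0.17 for hypoxia genes, 0.03 and -0.22 for autophagosome formation, and 0.04 and -0.18 for p53 targets. For lists the opposite direction is only the sign of the medians. Choosing by a large difference between responses also makes opposite signs more likely. In a single cell type only heat shock and hypoxia genes in neutrophils and autophagosome formation in monocytes stood apart. They did so under 2, 0 and 7 of 10 alternatives. The neutrophil medians of autophagosome formation and p53 targets lay at percentiles 60.5 and 61.3. These lists share some members.

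CD69, an early activation marker, was at 0.70 in neutrophils and -1.44 in monocytes, and the adaptor NCK1 at 0.69 and -1.34. For NCK1 the difference between responses fell from 2.02 to 0.73 with the mean of detected probes. In the other direction, ANKRD13D was at -1.34 and 0.69, EMX2OS at -0.72 and 1.15, PRPSAP2 at -1.02 and 0.61, and TMEM218 at -0.53 and 1.10.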

How the results depend on the processing

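The alternative of genes with a mean log2 of 7 or more was chosen after seeing the data and compares fewer genes by construction. No paired analysis was possible because each group has 1 array and the labels name no shared donor; the cell types are not replicates of each other. Of the 84 values of genes named by rank, none changed direction where it could be had. Of these, 64 could be had within each cell type and 54 at a mean log2 of 7 or more. A changed detection limit or filter, or the limit on mean log2, leaves the value of a gene as it is. Only the other alternatives could therefore have turned a direction, and the mean of detected probes only where a gene has a further detected probe. A further probe taken alone could differ in sign, as that of RNF19A did. All alternatives re-use the arrays on which these genes were chosen as extremes. The unchanged directions are therefore no independent support. Bounds and list members were not followed over the alternatives in this way. Of the 84, 8 fell short of 2-fold with an offset of 50 and 7 with the mean of detected probes. Counts below are genes 2-fold higher and lower. Otherwise the cause was not tested. With an offset of 50 the counts were 8 and 15 in neutrophils with CCCP, 19 and 76 in monocytes, and 65 and 34 for the difference between responses. A detection limit of 0.05 gave 56 and 73 in neutrophils. Detection on at least 1 array gave 185 and 195 in neutrophils, 475 and 370 for the difference, and 1773 lower between cell types. No detection filter gave 185 and 196, 489 and 388, and 1773, with a Pearson r of 0.073 between responses. The series matrix values gave 96 and 105 in neutrophils, 123 and 248 in monocytes, and 262 and 188 for the difference. A mean log2 of 7 or more gave 13 and 14 in neutrophils, 22 and 68 in monocytes, 796 and 500 between cell types, 77 and 40 for the difference, and a Pearson r of 0.219. The median of heat shock genes between cell types, -0.72, turned to 0.31 with the mean of detected probes and to 1.09 for genes of a mean log2 of 7 or more. Of 1160 list medians over the alternatives, 87 others moved by more than their spread, 39 of them nearer to 0 and 48 farther. Of 31 results in which a list stood apart (20 different lists over the 4 comparisons), 28 stood apart without background correction, 23 with an offset of 50, 23 with median centring, 25 at a detection limit of 0.05, 24 with detection on at least 1 array, 20 with no filter, 18 with the mean of detected probes and 24 from the series matrix values. Quantile normalization within each cell type left 13 of 18, and a mean log2 of 7 or more 14 of 30. Signal over background limits dim genes: only 19.0% to 25.9% of probes were detected.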

Other observations

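The grouping of small RNAs, and the tests of an equal loss of all short-lived mRNAs, of noise limited to named small RNAs and of noise as large as that of other probes, were chosen after the results were seen. The other tests here had their predictions written before their results. The prediction for noise of single probes was for a time replaced after its result was seen, then restored; the replacement is kept as the test of noise limited to named small RNAs.

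Small nuclear, nucleolar and Cajal body RNAs were higher in monocytes with CCCP. Over 38 detected genes the median log2 difference was 0.23 (percentile 99.9), with 11 genes 2-fold higher and none lower. In neutrophils the median over 33 genes was 0.03, with 1 gene 2-fold higher and none lower.

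No explanation of the small RNAs could be set aside. After the RNAs named by size in monocytes, U1 copies and further family members were left out, 30 small RNAs had a median of 0.09 in monocytes at percentile 85.49, between the bounds set, so noise limited to the named RNAs cannot be told apart. Of these 30, 4 were 2-fold higher (SCARNA9, SNORD35B, SNORD3A and SNORD89), and of 10000 random lists matched on expression 0 held as many. These 4 belong to the 11 that prompted the grouping, so the count decides nothing on noise as large as that of other probes of the same brightness. The median of the same RNAs in neutrophils (percentile 69.88) does not bear on noise of single probes in the monocyte arrays. Different capture of RNAs without a poly(A) tail cannot be told apart either, since replication-dependent histones, 7 detected members, lay at percentile 63.46, between the bounds set. A response of monocytes to CCCP is a hypothesis beside these.

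The lower NF-kappaB inflammatory genes in monocytes with CCCP (median -0.76) were weighed against technical and general explanations. A smaller share of monocytes would lower monocyte markers by about as much, and their lower quartile was -0.14. Noise of dim probes would leave bright members unshifted, and the 19 members with a mean log2 of 8 or more had a median of -0.55. An equal loss of all short-lived mRNAs would lower immediate early genes as far, and their lower quartile was -0.44. This shows only that most of these genes fell less than the NF-kappaB median. It does not decide on an equal loss, since the bound was set after the results were seen and levels do not separate loss from new synthesis. A general loss of short-lived mRNAs, equal or milder, cannot be told apart. The immediate early genes, which share no member with the NF-kappaB list, lay at percentile 3.64, between the bounds set. With such a loss open, a specific reduction of inflammatory transcripts may only be put forward as a hypothesis.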
